A study of Mus musculus with 4 samples.

How the data were processed

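Mouse kidney explants were profiled with the 10x Genomics single cell 3' v3 kit, per the labels, in 4 libraries: 2 at day 5 in Stage I medium and 2 at day 9 in Stage II medium. Per the labels' protocols, explants were digested with cold active protease and collagenase, and live single cells, negative for DAPI and positive for DRAQ5, were sorted before loading. Per the submitters' processing notes, reads were processed with Cell Ranger ARC 2.0.2 and STAR on the GRCm39 build. The deposited matrices hold raw UMI counts per gene and barcode, whole numbers, for 32287 features: 32285 Ensembl genes and the reporters tdTomato and Venus. The lowest total of a deposited barcode was 500 to 502 UMIs in the 4 libraries. The reference annotation at hand was of another build than GRCm39, so no coordinates are given.

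Barcodes were kept with at least 1000 genes and at most 15% mitochondrial UMIs. In the order day 5 replicates 1 and 2 and day 9 replicates 1 and 2, 556, 419, 510 and 1122 barcodes fell below the gene minimum, and 1010, 1123, 687 and 849 exceeded the mitochondrial limit. Doublets were scored per library with Scrublet as run in Scanpy 1.11.5 (Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, scikit-learn 1.9.0), and the share expected at 0.8% per 1000 barcodes was removed: 227, 372, 101 and 506 barcodes. Scrublet's automatic threshold marked 2, 208, 5 and 228. Kept cells had a median of 4960, 4669, 5028 and 3758 genes and of 5.10, 5.73, 6.34 and 5.85% mitochondrial UMIs. Between library pairs, 59, 47, 320, 86, 220 and 429 barcodes were shared. The distance between libraries in summed counts, as a chi-square per gene, was 54.0 between the day 5 replicates and 50.5 between the day 9 replicates, against 241 to 331 between days.

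Counts were scaled to 10000 UMIs per cell and log-transformed. Clustering used 2000 variable genes chosen with the library as batch, without mitochondrial, ribosomal protein, hemoglobin, Xist and Y-linked genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9), with no integration. Each of 33 clusters was named after the marker list with the highest mean log2 fold over the other cells, given at least 3 markers up, a mean of at least 1.0, detection in at least 10% of cells and a fold of at least 1.5. A cluster stayed without a name if its 10 leading genes held more markers of another class than of its own. It also did if its median UMI count was under 1 part in 3 of its libraries' medians and none of those 10 genes was a marker of its leading list. Clusters without a name, or led by the stromal progenitor or interstitial stroma list, were then compared with the clusters of the other named classes only, which named all stroma-like clusters as 1 class. The marker lists were fixed before the data were examined, and this naming rule was written after the clusters were seen. The UMI rule left out cluster 27, with 7 of 11 ureteric trunk and collecting duct markers up, a mean of 1.82 and a median of 5665 UMIs. It held 62 and 21 cells of the day 5 and 28 and 66 of the day 9 libraries. Cluster 32, with a median of 3215 UMIs, has the trunk markers Elf5 and Krt18 among its leading genes and was named. The rules named 30 clusters in 12 classes and left 3 without a name, and each class name ends in "-like" because it rests on markers alone. Classes with at least 50 cells in every library were compared within the class. The ureteric tip-like and the ureteric trunk and collecting duct-like classes each had under 50 cells in day 9 replicate 1 and were merged as ureteric epithelium-like cells, a choice made after their cell numbers were seen.

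Libraries, not cells, were the replicates. For all cells and each class, counts were summed per library, scaled with TMM, filtered with filterByExpr and tested with edgeR 4.0.16 quasi-likelihood fits (R 4.3.3), day 9 against day 5, with no replicate block. Benjamini-Hochberg adjustment was over the genes of a population, with calls at an adjusted p under 0.05. Cell numbers per class were tested with edgeR with the number of kept cells as library size. Gene lists, 20 of cell type markers in all cells and 20 of processes in all cells and each class, were tested with camera at a preset correlation of 0.01 in limma 3.58.1 on voom values, adjusted over the lists of a population; 4 listed genes matched no feature. Named genes were the 12 largest rises and 12 largest falls in all cells, and the 5 of each in a class, among called genes with a mean of at least 20 CPM and the libraries of the days apart, without predicted, Rik clone, mitochondrial, hemoglobin, Xist and Y-linked genes. Up to 4 members per list with the smallest p were eligible as examples; which of these are printed was chosen after their values were seen. Shares of single libraries carry exact Clopper-Pearson 95% intervals, and a count of 0 allows 3 counts of the total; both cover counting error only. The groups, tests, lists and rule for named genes were fixed before the data were examined.

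Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, a replicate block, no doublet removal, no cell filter, a stricter filter (2000 genes, 10% mitochondrial UMIs), equal weight per named class with at least 20 cells in every library (limma on log2(CPM + 1) of the mean CPM), Leiden resolutions 0.5 and 2.0, other sets of variable genes, each library clustered alone, TMM on cell numbers, an estimated correlation and fry for lists, and leaving out each library in turn. Without 1 library its day held a lone sample, assumed to vary like the other day's pair. The classes to compare were chosen in the main clustering, so in an alternative a class could hold under 50 cells in a library. Chosen after seeing the data were the runs without urothelium-like and smooth muscle-like cells, without barcodes holding at most 1 of every 10 UMIs of the same barcode in another library, with the ureteric classes or the larger nephron progenitor-like cluster alone, and the differences between classes.

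The tests were tested on simulated data with 100 genes changed at each fold. With edgeR in all cells, 64% were recovered at a log2 change of 1 and 94% at 2, with 23 false calls among 19761 genes. In nephron progenitor-like cells the figures were 69 and 95% with 17 false calls among 13474 genes, in podocyte-like cells 57 and 85% with 12 among 12128, and in proximal tubule-like cells 60 and 94% with 14 among 12960. In stroma-like cells they were 74 and 94% with 30 among 17155, and in ureteric epithelium-like cells 70 and 94% with 29 among 13885. In each of these populations false calls made up a larger share of all calls than the threshold on adjusted p allows. The share of false calls among the genes called in the explants may therefore exceed that threshold too. On cell numbers at a log2 change of 2, 98% of 100 changes were recovered over 50 simulations of 12 classes, with 10 false calls. There too the false calls were a larger share of all calls than the threshold allows. The spread of these simulated cell numbers was set by hand and not taken from the data, so that recovery need not hold for the explants. Of 10 changed lists in all cells, camera recovered 100% at the preset and 90% with an estimated correlation, with 0 false calls. Members of these lists were random genes drawn independently. The simulation therefore cannot show how either version behaves on lists whose members vary together. Figures were drawn with matplotlib 3.10.9.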

Results

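Single-cell transcriptomes were collected from mouse kidney explants, pieces of tissue kept in culture, in a series whose title names synthetic kidneys grown from kidney progenitors. The labels give wild-type explants at day 5 in Stage I medium and at day 9 in Stage II medium, with 2 libraries for each day, and state the purpose as profiling the cell populations at the 2 time points. Day and medium changed together, so each comparison was of day 9 in Stage II medium with day 5 in Stage I medium. At day 5, replicate 1 held 6001 deposited barcodes with 110125164 UMI counts and replicate 2 held 7535 with 132133513. At day 9, replicate 1 held 4014 barcodes with 75826177 counts and replicate 2 held 8879 with 108475807. After cell filters and doublet removal, 4494, 5792, 3033 and 6611 cells were kept in that order, 19930 in all, with median depths of 19371, 17636, 18740 and 10935 UMIs per cell. Gene levels are CPM, TMM-scaled, of counts summed over a library's cells, as mean ± SD of 2 libraries per day (n = 2). Changes are log2 fold changes of day 9 over day 5 ± SE, with Benjamini-Hochberg adjusted p from edgeR. Each gene named as risen or fallen had both libraries of 1 day above both of the other. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples. Loading days are not given either, so any difference in handling between the days cannot be told apart from day and medium. Genes carry the symbols and Ensembl identifiers of the deposited feature tables, which give no coordinates.

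Across all cells, early response transcription factor genes rose and neurofilament genes fell between the days. Zbtb16 (ENSMUSG00000066687), a zinc finger transcription factor gene, went from 0.708 ± 0.0967 to 94.3 ± 6.95 CPM, a log2 change of 7.06 ± 0.16 (adjusted p = 3.71e-05). The immediate early genes Fosb (5.13 ± 0.15), Fos (4.96 ± 0.16), Egr1 (3.83 ± 0.14), Egr3 (3.78 ± 0.14) and Nr4a1 (3.69 ± 0.24) rose, as did the transcription factor gene Klf2 (3.74 ± 0.21). The epithelial genes Ly6d (5.31 ± 1.24) and Sprr2f (4.19 ± 0.28) also rose, with Fmo5 (3.65 ± 0.51), Lmo1 (3.56 ± 0.28) and the muscle gene Pdlim3 (3.53 ± 0.46). Adjusted p for these 12 genes lay between 3.71e-05 and 0.0191. The neurofilament gene Nefm (ENSMUSG00000022054) fell from 208 ± 16.6 to 0.983 ± 0.153 CPM, a log2 change of -7.71 ± 0.17, and its partner Nefl by -7.07 ± 0.26. Ankrd37, a hypoxia-induced gene, fell (-4.48 ± 0.22), as did the transcription factor gene Osr2 (-3.74 ± 0.25) and the genes for the secreted factors Sostdc1 (-3.52 ± 0.54), Ccn2 (-3.17 ± 0.39), Inhba (-2.88 ± 0.15) and Cthrc1 (-2.88 ± 0.13). Clec18a (-2.80 ± 0.40), the heparan sulfate sulfotransferase gene Hs3st3b1 (-2.68 ± 0.21) and the receptor genes Tnfrsf12a (-2.68 ± 0.13) and Erbb4 (-2.63 ± 0.29) completed the 12 largest falls. Of 19761 genes tested, 7233 changed (3894 higher and 3339 lower at day 9). Day 5 replicate 2 held no cells of the urothelium-like or the mural and smooth muscle-like class. With those classes left out of every library, Ly6d stood at 4.02, Sprr2f at 3.81, Fmo5 at 1.94 and Pdlim3 at 3.89, and Lmo1 no longer passed (0.82, adjusted p = 0.0518).

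**Figure D1:**
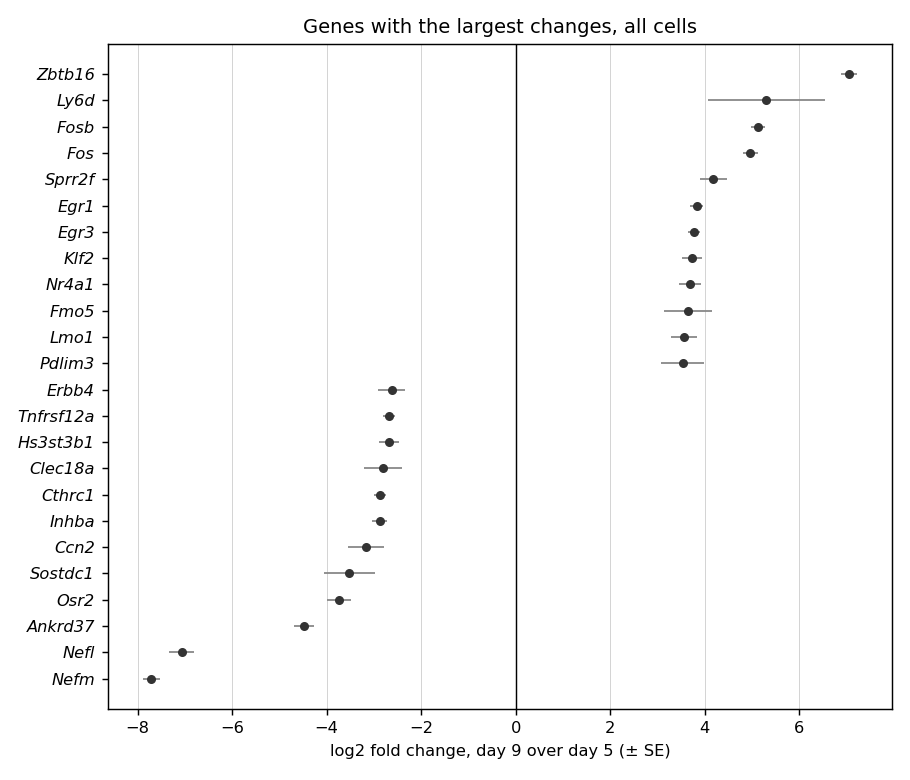
Log2 fold change (x axis) of the 24 genes with the largest changes in all cells (y axis), day 9 over day 5, from edgeR with 2 libraries per day. Points are estimates and lines are ± SE; Zbtb16 lies at 7.06 and Nefm at -7.71.

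The size of several of these changes rested on 1 library. Without day 5 replicate 1, Ly6d rose by 10.21, Fmo5 by 4.69 and Pdlim3 by 4.46; without day 5 replicate 2, Ly6d rose by 4.31 and Fmo5 by 3.04. Without day 9 replicate 2, the change was -4.66 for Sostdc1, -3.62 for Clec18a and -7.66 for Nefl, and without day 9 replicate 1 it was -2.92 for Sostdc1 and -3.84 for Ccn2. The number of changed genes was 4413 without day 5 replicate 1 and 2538 without day 5 replicate 2. With equal weight for each named class with at least 20 cells in every library, on log2(CPM + 1) with limma, 4327 genes changed (3161 higher, 1166 lower). That fit left out the loop of Henle-like, committing nephron-like, urothelium-like, mural and smooth muscle-like and endothelium-like classes and the cells without a name. There Zbtb16 stood at 4.16, Nefm at -5.09, Nefl at -3.88, Ly6d at 2.03, Fosb at 4.35, Fos at 3.96, Klf2 at 3.13, Egr3 at 2.92, Nr4a1 at 2.92, Pdlim3 at 2.89, Sprr2f at 4.93 and Fmo5 at 1.31. The falls there were -2.87 for Osr2, -1.67 for Sostdc1, -1.56 for Cthrc1, -1.05 for Tnfrsf12a, -1.04 for Hs3st3b1 and -1.02 for Clec18a. With a replicate block Ly6d stood at 6.10. In the equal weight fit Lmo1 (0.56), Ccn2 (-0.91) and Erbb4 (-0.32) no longer passed.

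Some metabolic, cell cycle and signalling lists passed in all cells with camera at the preset correlation, and none passed with an estimated correlation. All 18 cholesterol synthesis genes fell (18 adjusted over the list alone), among them Msmo1 (-2.18 ± 0.13), Lss (-2.14 ± 0.12) and Hmgcs1 (-2.01 ± 0.14; camera adjusted p = 1.85e-13). Of 17 glycolysis and hypoxia response genes, 15 fell and 1 rose (16 and 1 adjusted over the list alone), including Pdk1 (-1.86 ± 0.15), Bnip3 (-1.49 ± 0.11) and the glucose transporter gene Slc2a1 (-1.41 ± 0.14; adjusted p = 1.85e-07). With an estimated correlation, adjusted p = 0.682 for the first list and adjusted p = 0.550 for the second. Of 31 S phase genes, 23 fell (26 adjusted over the list alone), such as Rrm2 (-1.18 ± 0.12) and Mcm5 (-1.03 ± 0.12; adjusted p = 1.27e-08). Of 40 G2/M phase genes, 26 fell (28 adjusted over the list alone), such as Cdc20 (-1.09 ± 0.11; adjusted p = 1.17e-08). Of 12 Notch pathway genes, 9 fell (10 adjusted over the list alone), among them the target Hey1 (-2.06 ± 0.14) and the ligand gene Jag1 (-1.84 ± 0.12; adjusted p = 1.79e-05). Of 12 Wnt/beta-catenin targets, 4 fell (4 adjusted over the list alone), including Dkk1 (-5.10 ± 0.32), an inhibitor of the pathway, and Lgr5 (-1.78 ± 0.15; adjusted p = 0.00246). For each of these 4 lists, adjusted p = 0.487 with an estimated correlation. Immediate early and heat shock genes were higher as a list (adjusted p = 0.00732; adjusted p = 0.487 with an estimated correlation), with 8 of 12 up, such as Junb (2.90 ± 0.15), and 3 down, the same numbers as adjusted over the list alone. Extracellular matrix genes rose in 12 of 20 cases and fell in 3 (14 and 3 adjusted over the list alone), with Dcn at 1.99 ± 0.15, Col6a1 at 1.80 ± 0.14 and Bgn at 1.23 ± 0.14 (adjusted p = 0.00253). Of 12 interferon response genes, 6 rose (6 adjusted over the list alone), among them Bst2 (2.57 ± 0.13) and Oasl2 (2.09 ± 0.28; adjusted p = 0.00562). Of 16 fatty acid oxidation genes, 5 rose (5 adjusted over the list alone), such as Acaa2 (1.25 ± 0.10) and Cpt1a (1.24 ± 0.15; adjusted p = 0.0420, and adjusted p = 0.109 without day 9 replicate 2). Of 17 oxidative phosphorylation genes, 6 fell (6 adjusted over the list alone), such as Atp5b (-0.72 ± 0.13; adjusted p = 0.00259). Each of these 4 lists had adjusted p = 0.736 with an estimated correlation. FGF/ERK targets (2 higher and 2 lower of 11; adjusted p = 0.280), BMP and TGF-beta targets (3 higher and 5 lower of 12; adjusted p = 0.229) and retinoic acid response genes (3 higher and 2 lower of 8; adjusted p = 0.861) did not pass, with the same numbers adjusted over the list alone. Without day 9 replicate 1, Atp5b no longer passed (-0.69, adjusted p = 0.0537).

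Marker lists of the loop of Henle, committing nephron and proximal tubule were lower at day 9 in the summed counts, while those of the podocyte and distal tubule did not pass. Of 8 loop of Henle markers, 7 fell (7 adjusted over the list alone), such as Slc12a1 (-5.41 ± 0.26), the sodium-potassium-chloride cotransporter gene. Of 9 committing nephron markers 8 fell (8 adjusted over the list alone), such as Fgf8 (-2.49 ± 0.18) and Pax8 (-1.35 ± 0.14). Camera gave adjusted p = 1.79e-05 and 3.72e-05 for the 2 lists, and adjusted p = 0.487 with an estimated correlation for both. Of 12 proximal tubule markers, 5 fell and 1 rose (7 and 1 adjusted over the list alone), with the endocytic receptor gene Lrp2 at -2.46 ± 0.37 and the transcription factor gene Hnf4a at -2.39 ± 0.38 (adjusted p = 0.0136). Of 9 podocyte markers, 3 fell and 1 rose (3 and 2 adjusted over the list alone; adjusted p = 0.697), and of 5 distal tubule markers 2 fell (2 adjusted over the list alone; median 0.10, adjusted p = 0.540). Of 26 tubule transporter genes, 11 fell and 3 rose (11 and 3 adjusted over the list alone), including the epithelial sodium channel gene Scnn1g (-1.58 ± 0.16; adjusted p = 0.00732). Of 7 urothelium markers, 2 rose (2 adjusted over the list alone), one of them the keratin gene Krt5 (3.95 ± 0.56; adjusted p = 0.0420, and adjusted p = 0.0783 with a replicate block). The proximal tubule, transporter and urothelium lists each had adjusted p = 0.736 with an estimated correlation. In the fit with equal weight per class, which holds no loop of Henle-like, committing nephron-like or urothelium-like cells, Slc12a1 (-0.37), Fgf8 (-0.03), Pax8 (-0.40) and Krt5 (0.08) did not pass, nor did Mcm5 (-0.40) and Cdc20 (-0.33) of the cell cycle lists. In the same fit Dkk1 stood at -1.59, Lgr5 at -0.64, Lrp2 at -0.90, Hnf4a at -0.62, Bst2 at 0.94, Junb at 1.78, Acaa2 at 0.41, Jag1 at -1.07, Hey1 at -1.42, Oasl2 at 1.32 and Slc2a1 at -2.08. That fit changed the weights, the cells, the scale and the test at once, so none of these moves is put down to 1 of them. Without day 9 replicate 2, Lrp2 stood at -3.16, Hnf4a at -3.06 and Dkk1 at -5.74, and without day 5 replicate 1 Krt5 stood at 4.58. Over all deposited barcodes Slc12a1 stood at -2.42, Lrp2 at -1.79, Hnf4a at -1.69 and Sostdc1 at -2.37, and without urothelium-like and smooth muscle-like cells Scnn1g stood at -2.40. Of the 40 lists tested in all cells, 16 passed with camera, 11 with fry and 0 with an estimated correlation. Fry added the stromal progenitor (adjusted p = 0.0239) and skeletal muscle lists (0.0163) and lost the proximal tubule (adjusted p = 0.249), urothelium (0.292), fatty acid oxidation (0.0807), oxidative phosphorylation (0.206), matrix (0.116), interferon (0.149) and transporter lists (0.116).

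The explants held 12 named cell classes, and no class share passed the test between the days. Committing nephron-like cells made up 2.44% ± 0.0465 of kept cells at day 5 and 0.0151% ± 0.0214 at day 9 (mean ± SD, n = 2), a log2 difference of -6.84 ± 1.00 (adjusted p = 0.0562, edgeR on cell numbers). Loop of Henle-like cells went from 2.75% ± 0.366 to 0.410% ± 0.254 (-2.71 ± 0.61; adjusted p = 0.0686) and ureteric trunk and collecting duct-like cells from 5.72% ± 1.14 to 1.79% ± 0.338 (-1.68 ± 0.35; adjusted p = 0.0686). Podocyte-like cells went from 8.31% ± 2.46 to 2.78% ± 0.623 (-1.58 ± 0.41; adjusted p = 0.0770) and proximal tubule-like cells from 6.21% ± 1.17 to 2.44% ± 1.02 (-1.35 ± 0.46; adjusted p = 0.133). In each of these 5 classes both day 9 libraries lay below both day 5 libraries. The same held for the ureteric tip-like, endothelium-like and stroma-like classes, so this order was not particular to the 5. The committing nephron-like estimate moved to -6.23 without day 9 replicate 1 (adjusted p = 0.0348). The class also passed without day 9 replicate 2 (0.0254), with each library clustered alone (0.0203) and with variable genes without cell cycle lists (0.0149), but with 0 such cells left at day 9 these fits measured no size. It was -5.92 with variable genes without called genes (0.00296) and -5.42 with no doublet removal (0.0840). It also passed at Leiden resolutions 0.5 (0.0410) and 2.0 (0.0340), with the stricter cell filter (0.0480) and without day 5 replicate 1 (0.0480). With each library clustered alone, loop of Henle-like cells passed (adjusted p = 0.0205), again with 0 cells at day 9 and no size. Their estimate was -3.56 without day 9 replicate 2 (adjusted p = 0.0591), -1.80 with no doublet removal (0.0840), -1.57 at resolution 0.5 (0.0926) and -1.24 with variable genes without called genes (0.200). For the ureteric trunk it was -0.71 with each library clustered alone (adjusted p = 0.0408) and -2.48 with the stricter filter (0.0480), where loop of Henle-like cells also passed (-2.46, 0.0480). With variable genes without cell cycle lists, loop of Henle-like (-3.18, adjusted p = 0.0380), ureteric trunk-like (-1.86, 0.0380) and podocyte-like cells (-1.71, 0.0445) passed. Proximal tubule-like cells stood at -1.22 with each library clustered alone (adjusted p = 0.0203), -2.34 with the stricter filter (0.0771) and -1.98 with variable genes without called genes (0.188). Committing nephron-like cells numbered 0 of 3033 in day 9 replicate 1, which allows a share of up to 0.0989%, and 2 of 6611 in day 9 replicate 2 (0.0303%, exact 95% Clopper-Pearson interval 0.00366 to 0.109%). Nephron progenitor-like cells held 6.15% ± 0.588 at day 5 and 6.75% ± 0.00895 at day 9, and stroma-like cells, the most numerous class, 61.2% ± 1.11 and 55.8% ± 5.07. Ureteric tip-like cells went from 2.52% ± 0.244 to 1.82% ± 0.615, endothelium-like cells from 0.482% ± 0.168 to 0.177% ± 0.157, and macrophage and other leukocyte-like cells from 0.598% ± 0.0583 to 0.566% ± 0.179. Adjusted p for these 5 classes lay between 0.377 and 0.831 (edgeR).

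**Figure D2:**
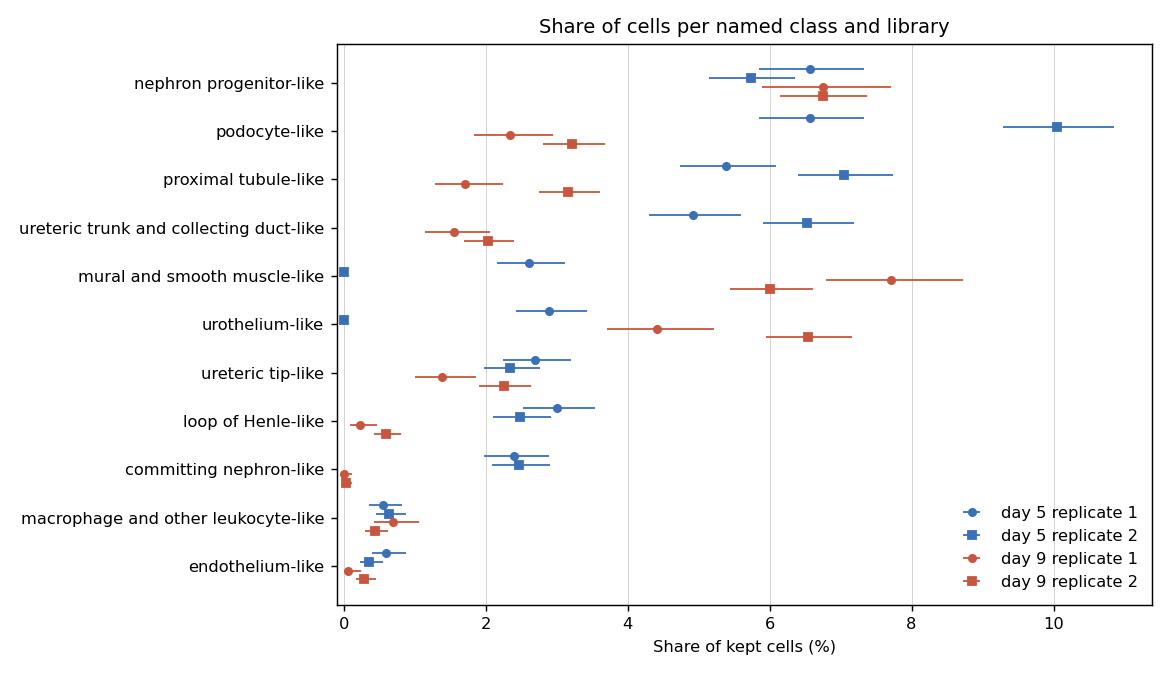
Share of kept cells in percent (x axis) for 11 named classes (y axis) in each of the 4 libraries; stroma-like cells, at 52.2 to 62.0%, are left out. Points are libraries, coloured by day, and lines are exact 95% Clopper-Pearson intervals, which cover counting error only; day 5 replicate 2 lies at 0 for the urothelium-like and the mural and smooth muscle-like classes.

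The urothelium-like and the mural and smooth muscle-like classes separated the day 5 replicates. Urothelium-like cells made up 2.89% of day 5 replicate 1 (exact 95% interval 2.42 to 3.43%) and 0 of 5792 cells of day 5 replicate 2, which allows up to 0.0518%, against 4.42 and 6.53% at day 9. Mural and smooth muscle-like cells made up 2.60% (2.16 to 3.11%) and 0 of 5792 cells at day 5, against 7.72 and 6.01% at day 9. The log2 differences were 1.92 (adjusted p = 0.642) and 2.40 (0.586) for these classes (edgeR). Without day 5 replicate 1, where the lone day 5 library held none of these cells, both passed (adjusted p = 0.0480 each) with no size measured. Without day 5 replicate 2 they were 0.93 (0.308) and 1.39 (0.166), and with a replicate block 4.45 (0.644) and 4.90 (0.560). The urothelium-like difference was 0.95 with the stricter cell filter (0.851). No class of 12 passed, with 4 at an unadjusted p under 0.05, and the smallest p of an exact permutation test of 2 against 2 libraries is 0.333. With the urothelium-like and smooth muscle-like cells left out, an alternative chosen after seeing the data, 5 of 10 classes passed: committing nephron-like (-6.58, adjusted p = 5.17e-08), loop of Henle-like (-2.45, 3.95e-05) and ureteric trunk and collecting duct-like (-1.51, 0.00131). So did podocyte-like (-1.41, 0.00143) and proximal tubule-like cells (-1.16, 0.00609), all by edgeR. Shares also carry the yield of the dissociation and of the sort for live single cells, and 13.7 and 16.5% of day 9 cells, against 1.40 and 0.363% at day 5, lay in clusters without a name.

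Stroma-like cells showed the largest number of changed genes among the classes. Zbtb16 rose by 9.68 ± 0.24, from 0.161 ± 0.0332 to 133 ± 21.1 CPM (adjusted p = 1.11e-08, edgeR). The alcohol dehydrogenase gene Adh1 (5.02 ± 0.19), the transporter gene Abcc4 (4.65 ± 0.15), the retinol-binding protein gene Rbp4 (4.54 ± 0.16) and Fos (4.47 ± 0.18) rose. The neurofilament genes Nefl (-9.45 ± 0.25) and Nefm (-9.11 ± 0.19) fell, the latter from 430 ± 21.4 to 0.779 ± 0.118 CPM. Ccn2 (-4.49 ± 0.23), Tnfrsf12a (-4.39 ± 0.15) and the tubulin gene Tubb2b (-4.34 ± 0.14) were the other large falls. Cell cycle genes fell in this class: 28 of 31 S phase genes (28 adjusted over the list alone), such as Rrm2 (-1.87 ± 0.16) and Mcm5 (-1.72 ± 0.16). So did 39 of 40 G2/M genes (39 adjusted over the list alone), such as Cdc20 (-1.62 ± 0.13) and Tacc3 (-1.40 ± 0.12). Camera gave adjusted p = 1.11e-13 and 7.31e-16, and with an estimated correlation adjusted p = 0.325 and adjusted p = 0.390. All 18 cholesterol synthesis genes fell (18 adjusted over the list alone), with Msmo1 at -2.44 ± 0.12 and Hmgcs1 at -2.12 ± 0.14. Of the glycolysis and hypoxia response genes, 14 of 17 fell while 2 rose (15 and 2 adjusted over the list alone), with Pdk1 at -2.97 ± 0.14 and Eno1 at -1.72 ± 0.13. Their adjusted p values were 2.47e-14 and 4.23e-07 with the preset, and adjusted p = 0.390 and adjusted p = 0.325 with an estimated correlation.

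Most of the matrix and fatty acid oxidation genes measured rose in the stroma-like class. Of 20 extracellular matrix genes, 13 rose and 3 fell (13 and 5 adjusted over the list alone), with Dcn at 1.88 ± 0.15 and Col6a2 at 1.66 ± 0.14 (camera adjusted p = 0.00648; adjusted p = 0.390 with an estimated correlation). Of 15 fatty acid oxidation genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone), with Cpt1a, the carnitine shuttle gene, at 2.11 ± 0.15 and Acaa2 at 1.57 ± 0.13 (adjusted p = 0.00494; adjusted p = 0.392 with an estimated correlation). Of 12 interferon response genes, 7 rose (7 adjusted over the list alone), led by Bst2 (3.21 ± 0.12; adjusted p = 0.00693; adjusted p = 0.625 with an estimated correlation). Of 12 immediate early and heat shock genes, 9 rose, such as Fosb (4.39 ± 0.15) and Egr1 (3.47 ± 0.16), and 3 fell, such as the heat shock gene Hspa1a (-2.92 ± 0.13), the same numbers as adjusted over the list alone (adjusted p = 0.00693; adjusted p = 0.390 with an estimated correlation). Of 10 Notch pathway genes, 6 fell (6 adjusted over the list alone), including Hey1 (-2.12 ± 0.17) and Jag1 (-1.62 ± 0.17; adjusted p = 0.00387; adjusted p = 0.390 with an estimated correlation). Of 17 oxidative phosphorylation genes, 7 fell (3 adjusted over the list alone), such as Cycs (-0.75 ± 0.13; adjusted p = 0.0209; adjusted p = 0.674 with an estimated correlation). This last call was lost without day 5 replicate 2 (adjusted p = 0.154), day 9 replicate 1 (0.213) or day 9 replicate 2 (0.0522). In all, 8162 of 17155 genes changed (4295 higher, 3867 lower), and 10 of 20 lists passed. The stroma-like cells of the 2 days lay in mostly separate clusters: clusters 0, 7, 9, 15, 19 and 20 held the bulk of those at day 9, and clusters 1, 2, 3, 6, 10, 16 and 23 those at day 5. Without day 9 replicate 1 and day 9 replicate 2, in turn, Nefl stood at -10.38 and -8.86. With no doublet removal Nefl stood at -8.56, Nefm at -8.43, Fosb at 5.06 and Fos at 5.21, and at Leiden resolution 0.5 Nefl stood at -8.54. Fry lost the oxidative phosphorylation (adjusted p = 0.182) and interferon lists (0.107).

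Nephron progenitor-like cells, marked by Six2 among others, had lower levels at day 9 of genes that lead the podocyte-like cluster. Hs3st3b1 fell from 54.4 ± 0.615 to 0.910 ± 0.310 CPM, a log2 change of -5.92 ± 0.23 (adjusted p = 1.31e-09, edgeR). The tight junction gene Cldn5 (-4.36 ± 0.33), Zfp385b (-4.16 ± 0.22), Lor (-3.63 ± 0.21) and the transcription factor gene Mef2c (-3.32 ± 0.19) fell. Of these, Hs3st3b1, Cldn5 and Zfp385b were among the 10 leading genes of the day 5 podocyte-like cluster. At least 2 of Hs3st3b1, Cldn5 and Ndnf were detected in 42 of 295 and 44 of 332 cells of the class at day 5, and in 2 of 205 and 9 of 446 at day 9. At day 5 few of these cells, 11.9 and 6.82%, had a Six2 UMI, against 77.5 and 85.4% of the rest of the class. Of the 446 and 450 Hs3st3b1 counts of the class at day 5, 47 and 45 lay in the larger of its 2 clusters. The largest rises were of immediate early genes: Fosb (5.26 ± 0.26), Fos (5.15 ± 0.31), Egr1 (4.04 ± 0.15), Junb (3.10 ± 0.21) and Btg2 (3.05 ± 0.15). As a list, 7 of 12 immediate early and heat shock genes rose and 3 fell, the same numbers as adjusted over the list alone (camera adjusted p = 5.43e-04; adjusted p = 0.523 with an estimated correlation). Of 18 cholesterol synthesis genes, 16 fell (16 adjusted over the list alone), with Idi1 at -1.57 ± 0.14 and Msmo1 at -1.44 ± 0.12 (adjusted p = 4.40e-16; adjusted p = 0.523 with an estimated correlation). Of 15 glycolysis and hypoxia response genes, 11 fell (12 adjusted over the list alone), with Slc2a1 at -1.22 ± 0.16 and the lactate dehydrogenase gene Ldha at -1.04 ± 0.12 (adjusted p = 7.67e-09; adjusted p = 0.468 with an estimated correlation). Of 11 BMP and TGF-beta targets, 5 fell (6 adjusted over the list alone), such as Bambi (-1.77 ± 0.18) and Id2 (-0.83 ± 0.12; adjusted p = 0.0218; adjusted p = 0.619 with an estimated correlation). The S phase list did not pass (4 of 31 lower, 3 adjusted over the list alone; adjusted p = 0.179). Nor did the G2/M list (2 higher and 2 lower of 40, as adjusted over the list alone; adjusted p = 0.769), in which Cenpf rose by 0.80 ± 0.14. In all, 2929 of 13474 genes changed (1491 higher, 1438 lower), and 4 of 20 lists passed. In the larger of its 2 clusters alone, chosen after seeing the data, Hs3st3b1 stood at -3.53, Cldn5 at -1.92 and Zfp385b at -1.72. The same genes stood at -2.83, -1.90 and -1.70 under the stricter cell filter, -3.29, -2.20 and -1.65 without low copies of shared barcodes, and -3.50, -2.18 and -2.11 with no doublet removal. In the larger cluster alone the BMP and TGF-beta list did not pass (adjusted p = 0.576; 0.0806 without day 5 replicate 1, 0.0937 without day 9 replicate 2 and 0.148 with fry), Bambi stood at -1.16 and Btg2 at 3.77. DESeq2 called 1616 genes and the fit without day 5 replicate 2 called 1569. Under the stricter filter Fosb stood at 6.02, Btg2 at 3.98 and Cenpf at 1.53, and Cenpf stood at 1.47 both at Leiden resolution 2.0 and without low copies. Fos stood at 6.52 without day 5 replicate 1 and at 4.44 without day 5 replicate 2, and Cldn5 at -3.74 without day 9 replicate 1 and -5.89 without day 9 replicate 2.

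In podocyte-like cells some early response genes rose, while all listed cholesterol synthesis genes and some Notch and BMP genes fell. Fosb (6.51 ± 0.40), the prostaglandin D synthase gene Ptgds (6.04 ± 0.32), Zbtb16 (5.25 ± 0.33), Flrt1 (5.23 ± 0.27) and Fos (5.11 ± 0.24) rose, Ptgds from 2.07 ± 0.532 to 141 ± 57.4 CPM (adjusted p = 8.87e-10, edgeR). The noncoding RNA gene Rmst (-5.47 ± 0.36), the neurotrophin gene Ntf3 (-5.43 ± 0.48), the chloride channel gene Cftr (-4.83 ± 0.36), the phosphatase gene Ptprt (-4.54 ± 0.39) and Nell1 (-4.52 ± 0.38) fell. Rmst went from 110 ± 35.3 to 2.39 ± 0.373 CPM. All 18 cholesterol synthesis genes fell (18 adjusted over the list alone), such as Msmo1 at -2.47 ± 0.18. Of 16 glycolysis and hypoxia response genes, 12 fell while 1 rose (13 and 2 adjusted over the list alone), with Hk2 at -3.57 ± 0.34 and Ldha at -1.83 ± 0.18. Of 11 BMP and TGF-beta targets, 7 fell (8 adjusted over the list alone), with Id2 at -2.68 ± 0.22 and Id3 at -1.77 ± 0.16. Camera gave adjusted p = 1.77e-17, 2.58e-06 and 3.11e-05 for these 3 lists, and adjusted p = 0.508 with an estimated correlation for each. Of 9 Notch pathway genes, 5 fell (5 adjusted over the list alone), such as Hey1 at -3.86 ± 0.40 (adjusted p = 0.00560). Of 8 Wnt/beta-catenin targets, 5 fell (5 adjusted over the list alone), with Axin2 at -2.12 ± 0.35 and Lef1 at -1.80 ± 0.28 (adjusted p = 0.0235). Of 9 FGF/ERK targets, 4 fell (4 adjusted over the list alone), with Il17rd at -2.38 ± 0.31 (adjusted p = 0.00501). The S phase list fell in 9 of 28 genes (9 adjusted over the list alone; Cdca7 -3.86 ± 0.46; adjusted p = 0.00306). The G2/M list fell in 6 of 27 (6 adjusted over the list alone; Hmgb2 -1.79 ± 0.19; adjusted p = 0.00183). For these 5 lists adjusted p = 0.508 with an estimated correlation. Fatty acid oxidation genes rose in 8 of 14 cases (8 adjusted over the list alone), with Cpt1a at 2.58 ± 0.25 and Acadl at 0.96 ± 0.17 (adjusted p = 0.00103). Of the immediate early and heat shock genes, 7 of 12 rose while 3 fell, the same numbers as adjusted over the list alone, with Egr1 at 4.66 ± 0.24 (adjusted p = 0.00643). Both lists had adjusted p = 0.508 with an estimated correlation. Of 17 oxidative phosphorylation genes, 4 fell (0 adjusted over the list alone), such as Uqcrfs1 (-0.64 ± 0.20; adjusted p = 0.00643; adjusted p = 0.518 with an estimated correlation).

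In the podocyte-like class 3907 of 12128 genes changed (2083 higher, 1824 lower; 2502 by DESeq2), and 11 of 20 lists passed. Cluster 5, led by Arhgap29, Clic5 and Cldn5, held 99.8% of these cells at day 5 and 26.8% at day 9. Cluster 26, led by Mapt, Ptpro and the basement membrane collagen gene Col4a3, held 73.2% at day 9. Several list calls rested on 1 library: without day 5 replicate 1, adjusted p = 0.0788 for the Wnt/beta-catenin list, 0.0788 for the G2/M list and 0.0681 for the Notch list. With a replicate block the Wnt/beta-catenin list did not pass (adjusted p = 0.0550). Fry lost it too (0.0854), with the G2/M (0.141), fatty acid oxidation (0.0512), oxidative phosphorylation (0.202), FGF/ERK (0.185), Notch (0.141), BMP and TGF-beta (0.0512) and immediate early lists (0.0717). Without day 9 replicate 2 it was 0.126 for the Notch list and 0.174 for the FGF/ERK list. The oxidative phosphorylation list was lost without day 5 replicate 2 (adjusted p = 0.0890) and without day 9 replicate 1 (0.152), as was Uqcrfs1 (-0.55, adjusted p = 0.0615, and -0.39, adjusted p = 0.202). Ntf3, with 10 counts in day 9 replicate 1 and 0 in day 9 replicate 2, did not pass with DESeq2 (adjusted p = 0.118) and stood at -3.97 without day 9 replicate 2. It had 0 counts left at day 9 without day 9 replicate 1, so no size was measured there. Without day 9 replicate 1, Hk2 stood at -4.52 and Cdca7 at -4.58; without day 9 replicate 2, Hk2 stood at -2.72, Cdca7 at -3.12 and Lef1 at -2.87. Ptprt stood at -7.41 there, on 1 count in day 9 replicate 1. Zbtb16 stood at 5.85 without day 5 replicate 1 and at 4.58 without day 5 replicate 2, where Fosb stood at 5.92. Ptgds stood at 5.36 with the stricter cell filter, which left 45 cells of the class in day 9 replicate 1. Nell1 stood at -3.77 with no doublet removal.

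Proximal tubule-like cells had higher levels at day 9 of some genes of tubule injury, of epithelial junctions and of collecting duct principal cells. Lcn2 (ENSMUSG00000026822), which encodes the injury marker lipocalin 2, went from 0.200 ± 0.283 to 96.1 ± 32.1 CPM; with 3 counts at day 5, its ratio was 584 (95% counting interval 199 to 2842). Spp1, the osteopontin gene, rose by 6.74 ± 0.32, from 14.1 ± 6.51 to 1539 ± 461 CPM (adjusted p = 5.80e-11, edgeR), and the proton pump gene Atp6v0d2 (7.31 ± 0.41), Fosb (5.99 ± 0.31) and Lgals3bp (5.58 ± 0.31) rose. The metallothionein gene Mt2 (-3.73 ± 0.34), Galntl6 (-3.95 ± 0.30), the carboxypeptidase gene Cpb2 (-4.25 ± 0.34) and Ankrd37 (-4.79 ± 0.29) fell. Plcxd3, with 2 counts at day 9, was 113 times higher at day 5 (95% counting interval 31.2 to 937). Of 9 tubule injury genes, 6 rose, such as Krt20 (5.17 ± 0.26), and 3 fell, such as Clu (-1.88 ± 0.19), the same numbers as adjusted over the list alone (camera adjusted p = 0.00470). Of 13 epithelial junction and polarity genes, 8 rose (9 up and 1 down adjusted over the list alone), with the claudin genes Cldn3 at 4.30 ± 0.22 and Cldn4 at 3.94 ± 0.31 and the keratin gene Krt19 at 2.58 ± 0.30 (adjusted p = 5.30e-06). For these 2 lists adjusted p = 0.314 with an estimated correlation. Principal cell genes rose in 3 of 4 (3 adjusted over the list alone), such as the sodium channel gene Scnn1a (2.24 ± 0.47; adjusted p = 0.0175; adjusted p = 0.323 with an estimated correlation). The reporter Venus had a UMI in 77.6 to 100% of ureteric tip-like and trunk-like cells per library. It had one in 0 of 52 and 0 of 209 proximal tubule-like cells of the day 9 libraries, which allows up to 5.77 and 1.44%. At Leiden resolution 2.0 the class held 31 and 176 day 9 cells, against 52 and 209 in the main clustering. Lcn2 then had 160 and 96 counts at day 9, against 179 and 344, and Atp6v0d2 had 19 and 100, against 102 and 192. Part of these counts thus lay in cells that the finer clustering did not name proximal tubule-like. Whether the remaining rises came from change within proximal tubule cells or from other tubule cells grouped with them was not tested. All 18 cholesterol synthesis genes fell (18 adjusted over the list alone), with Insig1 at -2.86 ± 0.23 and Msmo1 at -2.66 ± 0.22. Of 16 glycolysis and hypoxia response genes, 10 fell (11 adjusted over the list alone), among them Ankrd37 and, with a smaller fall, Slc2a1 at -1.83 ± 0.20. Camera gave adjusted p = 3.15e-25 and 1.83e-07, with adjusted p = 0.314 for both with an estimated correlation. Of 11 Notch pathway genes, 6 fell (9 adjusted over the list alone), with Dll1 at -3.08 ± 0.36 and Hey1 at -2.38 ± 0.38 (adjusted p = 2.80e-05; adjusted p = 0.322 with an estimated correlation). Of 12 Wnt/beta-catenin targets, 6 fell (6 adjusted over the list alone), with Lgr5 at -2.77 ± 0.31 and Dkk1 at -2.32 ± 0.27 (adjusted p = 0.00422; adjusted p = 0.475 with an estimated correlation).

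Parts of other lists also moved in the proximal tubule-like class. Fatty acid oxidation genes rose in 6 of 15 cases (7 up and 1 down adjusted over the list alone), such as Pdk4 at 2.32 ± 0.41 (camera adjusted p = 0.00769; adjusted p = 0.314 with an estimated correlation). Of 12 immediate early and heat shock genes, 7 rose and 2 fell, as adjusted over the list alone, with Egr1 at 2.77 ± 0.22 and Atf3 at 2.61 ± 0.19 (adjusted p = 0.00151; adjusted p = 0.323 with an estimated correlation). Of 6 interferon response genes, 5 rose (6 adjusted over the list alone), such as Irf7 (2.52 ± 0.46; adjusted p = 0.00184; adjusted p = 0.314 with an estimated correlation). Matrix genes rose in 6 of 15 cases (6 adjusted over the list alone), such as Dcn (2.20 ± 0.41; adjusted p = 0.00678; adjusted p = 0.490 with an estimated correlation). The S phase list fell in 7 of 29 genes (7 adjusted over the list alone; Cdca7 -1.82 ± 0.30; adjusted p = 0.00400; adjusted p = 0.545 with an estimated correlation). The G2/M list fell in 8 of 33 (8 adjusted over the list alone; Hmgb2 -1.24 ± 0.19; adjusted p = 0.00162; adjusted p = 0.475 with an estimated correlation). At day 9 the level of Lcn2 was 382 ± 10.4 CPM in ureteric epithelium-like cells and 0.817 ± 0.357 CPM in stroma-like cells of the same libraries. In all, 2948 of 12960 genes changed (1686 higher, 1262 lower), and 13 of 20 lists passed. Cluster 13, led by Lrp2, Hdc and Slc34a1, held 98.9% of these cells at day 5, and cluster 24, led by Sult1d1, Cd74 and Spp1, held 96.6% at day 9.

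Proximal tubule-like calls leaned on single libraries. Genes called numbered 2038 without day 5 replicate 1, 1574 without day 5 replicate 2, 2659 without day 9 replicate 1 and 1910 without day 9 replicate 2, against 1779 by DESeq2 with all libraries. Lists passing numbered 14, 12, 12 and 9 in the same order. Leaving out day 9 replicate 2 gave the fewest lists, and the fatty acid oxidation (adjusted p = 0.1004), Wnt/beta-catenin (0.130) and matrix lists (0.429) were lost. Irf7 (1.83, adjusted p = 0.130) and Dcn (1.25, adjusted p = 0.114) did not pass without it. Without it, Lgals3bp stood at 4.96, Lgr5 at -2.07 and Mt2 at -2.99, while without day 9 replicate 1 Mt2 stood at -4.51 and Krt19 at 1.98. The S phase list was lost without day 9 replicate 1 (adjusted p = 0.0944), and the principal cell list without day 5 replicate 2 (0.253), day 9 replicate 1 (0.307) or day 9 replicate 2 (0.429). Scnn1a no longer passed without day 5 replicate 2 (1.84, adjusted p = 0.0900), with no doublet removal (0.78, adjusted p = 0.394) or at Leiden resolution 2.0 (0.63, adjusted p = 0.517). Krt19 no longer passed with the stricter cell filter (0.88, adjusted p = 0.113). Fry lost the S phase (adjusted p = 0.280), G2/M (0.207), Wnt/beta-catenin (0.126), Notch (0.0880), matrix (0.146) and principal cell lists (0.0503). Lcn2 stood at 7.76 without day 5 replicate 2, on 3 counts at day 5. Without day 5 replicate 1 Lcn2 had 0 counts left at day 5, and without day 9 replicate 2 Plcxd3 had 0 left at day 9, so neither fit measured a size. With the stricter filter Lcn2 had 0 and 31 counts at day 9, against 179 and 344 before it, and the low-count filter removed it, so its rise was not tested there. Scnn1a was not tested there either. Plcxd3 had 0 counts at day 9 with that filter, and Atp6v0d2 stood at 5.27, on 1 and 28 counts at day 9. With the same filter the class held 17 and 85 day 9 cells, the first below the minimum of 50. Lgals3bp stood there at 4.87, Cldn3 at 3.63, Cldn4 at 3.04 and Dcn at 2.93. Lgr5 stood at -4.26 and Galntl6 at -4.83, each on 0 and 10 counts at day 9, and Dkk1 at -4.32, on 0 and 3. The sizes of these last falls rest on few counts. With no doublet removal Lcn2 stood at 7.96, Atp6v0d2 at 6.39, Plcxd3 at -5.75, Cpb2 at -3.59, Cldn4 at 2.90, Krt19 at 1.06 and Lgr5 at -3.80. At Leiden resolution 2.0 Atp6v0d2 stood at 6.13, Krt19 at 1.24 and Lgr5 at -3.77. Atp6v0d2 stood at 8.34 without day 5 replicate 2, and Dcn at 2.85 without day 5 replicate 1 and 1.59 without day 5 replicate 2.

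Ureteric epithelium-like cells, the ureteric tip-like and the ureteric trunk and collecting duct-like cells as 1 class, gained some injury genes and lost hypoxia response genes. The epithelial gene Sprr2f rose from 68.6 ± 9.80 to 1785 ± 279 CPM, a log2 change of 4.70 ± 0.18 (adjusted p = 2.81e-06, edgeR). The phosphodiesterase gene Pde10a (4.10 ± 0.29), the water channel gene Aqp2 (4.02 ± 0.69), Atf3 (3.90 ± 0.47) and Egr1 (3.77 ± 0.28) rose. The hypoxia-induced genes Ankrd37 (-5.23 ± 0.21), Adm (-3.79 ± 0.21) and P4ha1 (-3.22 ± 0.17) fell, with the imprinted growth genes H19 (-3.57 ± 0.22) and Igf2 (-3.15 ± 0.18). Ankrd37 went from 110 ± 11.6 to 2.75 ± 0.759 CPM. All 16 measured glycolysis and hypoxia response genes fell (16 adjusted over the list alone), with Slc2a1 at -3.09 ± 0.14 and Egln3 at -2.25 ± 0.14. Of 18 cholesterol synthesis genes, 17 fell (17 adjusted over the list alone), with Mvd at -2.29 ± 0.14 and Fdft1 at -1.86 ± 0.13. Camera gave adjusted p = 8.52e-20 and 5.21e-21, and with an estimated correlation adjusted p = 0.473 and adjusted p = 0.480. Of 9 tubule injury genes, 7 rose and 1 fell (7 and 2 adjusted over the list alone), with Lcn2 at 3.27 ± 0.21, Vcam1 at 3.14 ± 0.37, Spp1 at 2.46 ± 0.21 and Clu at 0.97 ± 0.12 (adjusted p = 1.46e-04; adjusted p = 0.473 with an estimated correlation). Of 40 G2/M genes, 25 rose (33 adjusted over the list alone), with Mki67 at 1.25 ± 0.14 and Top2a at 1.13 ± 0.13 (adjusted p = 3.72e-15). Of 31 S phase genes, 8 rose (11 adjusted over the list alone), with Pola1 at 0.75 ± 0.14 and Hells at 0.64 ± 0.13 (adjusted p = 4.93e-05). Both had adjusted p = 0.480 with an estimated correlation. Of 12 p53 targets, 5 rose (6 adjusted over the list alone), with Eda2r at 2.68 ± 0.35 and Ccng1 at 0.83 ± 0.13 (adjusted p = 0.0152; adjusted p = 0.480 with an estimated correlation). Of 9 interferon response genes, 3 rose (5 adjusted over the list alone), such as Ifitm3 (1.03 ± 0.16; adjusted p = 0.00158; adjusted p = 0.473 with an estimated correlation). Of 12 immediate early and heat shock genes, 7 rose and 1 fell, as adjusted over the list alone, with Fosb at 5.14 ± 0.35 (adjusted p = 0.00112; adjusted p = 0.536 with an estimated correlation). Of 11 BMP and TGF-beta targets, 4 fell (4 adjusted over the list alone), with Smad7 at -1.12 ± 0.15 and Smad6 at -1.01 ± 0.16 (adjusted p = 0.00359; adjusted p = 0.536 with an estimated correlation). Of 17 oxidative phosphorylation genes, 4 fell (6 adjusted over the list alone), such as Atp5b (-0.61 ± 0.13; adjusted p = 8.06e-04; adjusted p = 0.536 with an estimated correlation). The principal cell list did not pass (2 higher and 3 lower of 11, 2 and 4 adjusted over the list alone; adjusted p = 0.177), with Scnn1g at -1.66 ± 0.16.

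The 2 ureteric classes differed from their sum. The class held 257 tip-like and 599 trunk-like cells at day 5, and 191 and 181 at day 9, so their mix moved with the day. In tip-like cells alone the G2/M list passed (adjusted p = 2.06e-05), and in trunk-like cells alone it did not (adjusted p = 0.930), where Mki67 stood at -0.08 and Top2a at -0.63. The S phase list passed in neither (0.709 and 0.467). The injury list passed in both (0.0384 in tip-like and 4.77e-05 in trunk-like cells). Lists within these single classes were tested with camera at the preset correlation only, and an estimated correlation was not run there. Tip-like cells alone gave -1.72 for Sprr2f (adjusted p = 0.0562), and Spp1 (0.85), Top2a (0.60), Ccng1 (0.15), Smad7 (-0.34), Smad6 (-0.27), Atp5b (-0.40), Pola1 (0.35) and Hells (0.13) did not pass there. Nor did the p53 (0.354), BMP and TGF-beta (0.823), interferon (0.185) and oxidative phosphorylation lists (0.137). In trunk-like cells alone Pola1 did not pass either (0.70, adjusted p = 0.0508). In all, 2217 of 13885 genes changed in the ureteric epithelium-like class (1173 higher, 1044 lower), and 10 of 20 lists passed. That count was 792 in tip-like cells alone, 1406 by DESeq2, 1069 without day 5 replicate 1, 768 without day 5 replicate 2 and 3326 without day 9 replicate 1. Aqp2 had 42 counts in day 9 replicate 1 and 656 in day 9 replicate 2, and stood at 4.76 without the former and 1.81 without the latter, and Atf3 stood at 2.92 and 4.57. The BMP and TGF-beta (adjusted p = 0.119) and p53 lists (0.0576) were lost without day 9 replicate 2. Pola1 (adjusted p = 0.0574 and 0.0843), Hells (0.0976 and 0.0914) and Atp5b (0.0588 and 0.0874) did not pass without day 5 replicate 1 or 2, and Ccng1 did not with the stricter cell filter (0.20, adjusted p = 0.395). Fry lost the S phase (0.0527), G2/M (0.0793), oxidative phosphorylation (0.136), BMP and TGF-beta (0.184), immediate early (0.184) and interferon lists (0.0504). With no doublet removal Pde10a stood at 2.37, Vcam1 at 2.47 and Eda2r at 1.91, and at Leiden resolution 2.0 Egr1 stood at 4.98. The stricter filter left 26 tip-like and 14 trunk-like cells in day 9 replicate 1. With it Sprr2f stood at 2.66, Pde10a at 3.16, Aqp2 at 2.98, Spp1 at 1.69, Ankrd37 at -5.90 and Egln3 at -3.04. In tip-like cells alone Lcn2 stood at 2.17, Egr1 at 5.61, Fosb at 4.05, Pde10a at 1.92 and Atf3 at 2.69. In trunk-like cells alone Pde10a stood at 5.68, Atf3 at 4.53, Vcam1 at 3.80, Lcn2 at 4.36 and Fosb at 5.79.

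**Figure D3:**
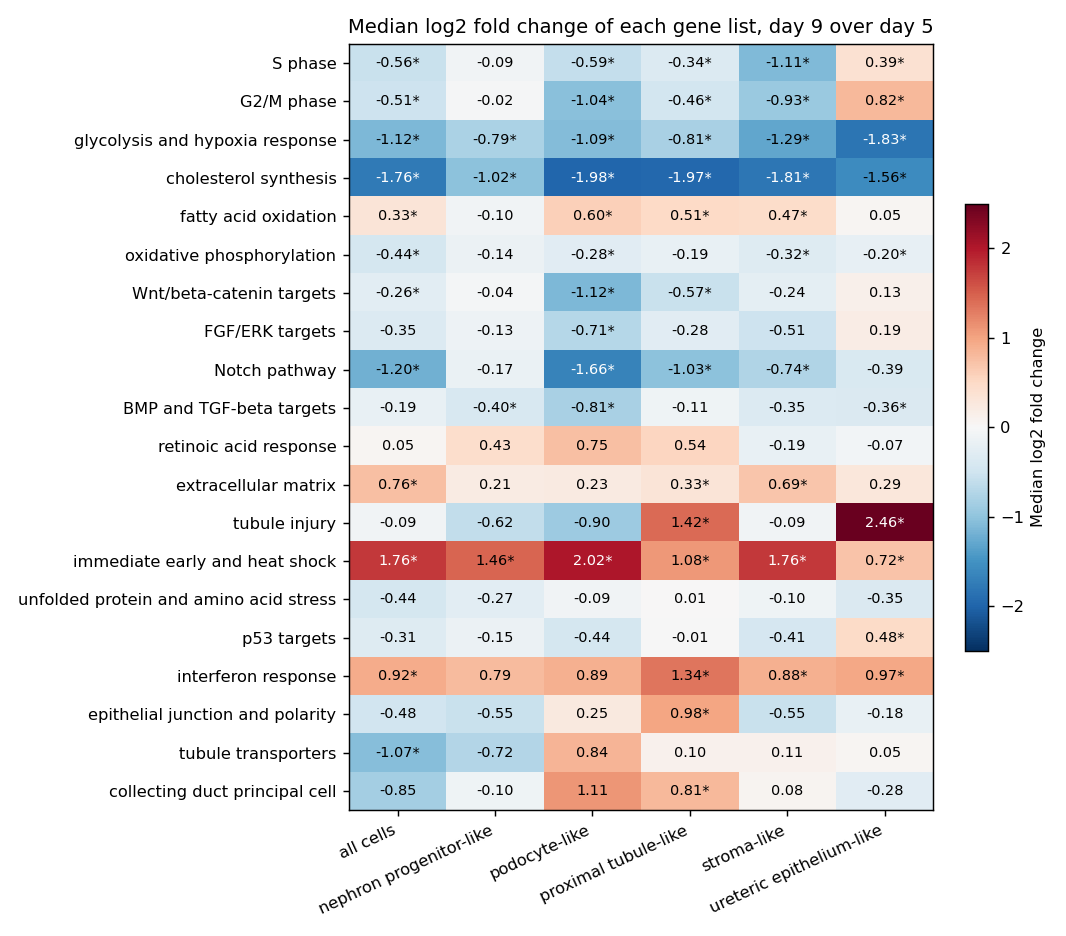
Median log2 fold change of the members of 20 gene lists (y axis), day 9 over day 5, in all cells and in 5 classes (x axis), by colour and number. An asterisk marks an adjusted p under 0.05 with camera at the preset correlation; no list passed with an estimated correlation. The cholesterol synthesis row runs from -1.02 to -1.98.

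Among lists that did not pass, the median, the mean and the camera direction differed in sign for 4 in all cells: distal tubule (median 0.10, mean -1.30, adjusted p = 0.540), ureteric tip (0.11, -0.25, 0.896), cartilage (-0.11, 0.09, 0.915) and tubule injury (-0.09, 0.50, 0.852). They also differed for fatty acid oxidation in nephron progenitor-like cells (-0.10, -0.14, tested up, 0.831), and for unfolded protein stress (0.01, 0.08, tested down, 0.954) and p53 targets (-0.01, 0.08, 0.743) in proximal tubule-like cells. In stroma-like cells they differed for retinoic acid response (-0.19, 0.36, 0.828) and tubule injury (-0.09, 0.46, 0.601), and in ureteric epithelium-like cells for retinoic acid response (-0.07, 0.14, 0.631) and tubule transporters (0.05, 0.30, tested down, 0.376).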

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

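The tests of differences between classes, of the missing urothelium-like and smooth muscle-like cells and of the podocyte genes were chosen only after the result was seen. Those of the cholesterol and hypoxia genes were not.

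Venus, a reporter in the deposited features and in no fixed list, had a UMI in 91.4% of ureteric epithelium-like cells and in 0.519% of stroma-like cells (median depths 27122 and 13998 UMIs), or 54.2 and 0.175% with each cell thinned to 5000 UMIs. The reporter tdTomato had a UMI in 32.6% of proximal tubule-like cells and in 1.05% of stroma-like cells (median depths 28683 and 13998 UMIs), or 9.39 and 0.339% after thinning, in explants labelled wild type. In proximal tubule-like cells that share was 28.5 and 28.9% in the day 5 and 48.1 and 40.7% in the day 9 libraries (6.19, 5.22, 16.3 and 16.6% after thinning), and tdTomato rose by 1.41 ± 0.21 (edgeR adjusted p = 7.66e-05). S phase genes changed less in nephron progenitor-like than in stroma-like cells, with a median difference of 0.91 and 31 of 31 genes higher (limma camera on the difference, adjusted p = 2.80e-10; adjusted p = 0.414 with an estimated correlation). For G2/M genes the difference was 0.90, with 40 of 40 genes higher (adjusted p = 1.05e-11; adjusted p = 0.414 with an estimated correlation). Ureteric epithelium-like cells differed from stroma-like cells by 1.57 for S phase genes, with 31 of 31 higher (adjusted p = 8.06e-15; adjusted p = 0.142 with an estimated correlation). Their G2/M genes differed by 1.77, with 40 of 40 higher (adjusted p = 1.47e-19; adjusted p = 0.414 with an estimated correlation). Tubule injury genes of the class differed by 1.59, with 8 of 9 higher (adjusted p = 0.00770; adjusted p = 0.414 with an estimated correlation). The mix of tip-like and trunk-like cells in this class moved with the day, from 257 and 599 to 191 and 181. Against stroma-like cells, tip-like cells alone differed by 1.11 for S phase (adjusted p = 1.63e-10) and 1.26 for G2/M genes (1.96e-18), and trunk-like cells alone by 1.28 (7.92e-09) and 1.17 (6.42e-07). With an estimated correlation these had adjusted p = 0.277, 0.137, 0.137 and 0.137. Injury genes differed by 2.10 in trunk-like cells (adjusted p = 3.36e-04; adjusted p = 0.137 with an estimated correlation) and by 0.13 in tip-like cells, which did not pass (adjusted p = 0.257). Of the change within a class, with camera at the preset correlation only, the G2/M list passed in tip-like cells alone (adjusted p = 2.06e-05) and not in trunk-like cells (0.930). The S phase list passed in neither (0.709 and 0.467). The other 7 of the 12 differences from stroma-like cells did not pass. In proximal tubule-like cells they were 1.62 for injury (adjusted p = 0.0942), 0.27 for S phase (0.233) and 0.18 for G2/M genes (0.470), and in podocyte-like cells -0.24 (0.484), 0.44 (0.183) and 0.08 (0.722). In nephron progenitor-like cells it was 0.50 for injury genes (0.345).

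Day 5 replicate 2 held no urothelium-like or smooth muscle-like cells, where day 5 replicate 1 held 247. At that share 318 were expected, so too few cells sampled is argued against. The cell filters, doublet removal and clustering are argued against too, as the cause of most of the absence. The share of all deposited barcodes with 3 UMIs or more of each of 2 marker genes was 2.34% of that in day 5 replicate 1 (6 of 7535 against 204 of 6001 barcodes). Other settings did name a few cells in day 5 replicate 2. With variable genes without cell cycle lists 17 were urothelium-like, against 186 in day 5 replicate 1. Smooth muscle-like cells numbered 5 at Leiden resolution 0.5, 4 at 2.0, 3 with variable genes without called genes and 5 with no doublet removal. That last run also named 2 urothelium-like cells. A swap with a day 9 library is argued against by the stroma-like cells of day 5 replicate 2, of which 99.9% lay in clusters where day 5 replicate 1 held the larger share. Differences in dissection or explant make-up stay open, and no biological explanation was tested, since the labels give none.

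Genes of the day 5 podocyte-like cluster were higher at day 5 in nephron progenitor-like cells. Free RNA from podocytes is argued against: the median ratio of the 10 genes to ureteric trunk-like cells of the same library was 7.69 in day 5 replicate 1 and 6.76 in day 5 replicate 2. A candidate explanation is that cycling cells of the podocyte lineage were grouped with the progenitors: of the cells with at least 2 of Hs3st3b1, Cldn5 and Ndnf, 11.9 and 6.82% had a Six2 UMI, against 77.5 and 85.4% of the rest. Of these 42 and 44 cells, 35 and 35 lay in the cycling cluster. At day 9 there were 2 of 205 and 9 of 446 such cells, so part of the falls may come from fewer of them. The larger, non-cycling cluster held 7 and 9 of them at day 5 and 2 and 6 at day 9. In it alone Hs3st3b1 still fell by -3.53 (edgeR adjusted p = 3.39e-05), Cldn5 by -1.92 (0.00664) and Zfp385b by -1.72 (0.00523), so change within progenitors stays open too.

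The cholesterol synthesis and the glycolysis and hypoxia response lists were lower in each class tested with camera at the preset correlation, and in none with an estimated correlation (smallest adjusted p = 0.314). Of the hypoxia genes, 11 of 15 were called lower in nephron progenitor-like, 12 of 16 in podocyte-like (1 higher), 10 of 16 in proximal tubule-like, 14 of 17 in stroma-like (2 higher) and 16 of 16 in ureteric epithelium-like cells. Adjusted over the list alone these were 12, 13 (2 higher), 11, 15 (2 higher) and 16. Of 18 cholesterol genes, 16, 18, 18, 18 and 17 were called lower in that order, as adjusted over the list alone. Free RNA from stroma-like cells is argued against: for 100% of the 33 members called lower in ureteric epithelium-like cells, the fall exceeded 1 part in 10 of the day 5 level in stroma-like cells. A shift of all genes by the scaling is argued against, since the members' median lay below that of all genes in 6 of 6 populations, with a smallest gap of -0.96. Camera had already set these lists against other genes on the same values, so the gap is not separate support. The change of medium and the days in culture cannot be told apart, since 0 days had libraries in both media. Biological change with day stays open and untested apart from the medium.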

How the results depend on the processing

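The runs without urothelium-like and smooth muscle-like cells, without low copies of shared barcodes, and with single ureteric classes or the larger nephron progenitor-like cluster were chosen only after the result was seen. For 184 single genes, 2425 of 2464 values under an alternative kept direction and side of the threshold, 36 kept the direction without passing and 3 reversed: in tip-like cells alone Sprr2f was -1.72, and in trunk-like cells alone Mki67 was -0.0841 and Top2a -0.63. For 64 list calls, 410 of 536 values kept both, 124 no longer passed (64 with an estimated correlation, 30 with fry) and 2 reversed in tip-like cells alone, BMP and TGF-beta targets up (adjusted p = 0.823) and p53 targets down (adjusted p = 0.354, signed as -0.354 for its direction). With an estimated correlation 0 lists passed in each of the 6 populations (smallest adjusted p = 0.314). Fry kept 9 of 16 in all, 3 of 4 in nephron progenitor-like, 3 of 11 in podocyte-like, 7 of 13 in proximal tubule-like, 8 of 10 in stroma-like and 4 of 10 in ureteric epithelium-like cells. It added 2 in all cells, in podocyte-like cells retinoic acid response (adjusted p = 0.00374), p53 targets (0.0271), interferon response (0.0388) and tubule transporters (0.0271), and in proximal tubule-like cells retinoic acid response (0.0383). In stroma-like cells it added Wnt/beta-catenin (0.0485), BMP and TGF-beta (0.0374) and unfolded protein lists (0.00615). Tip-like cells alone gave 6 with camera at the preset correlation. Counts of changed genes moved to 4327 in all cells with equal weight per class, to 792 in tip-like cells alone, and with DESeq2 to 1616 in nephron progenitor-like, 2502 in podocyte-like, 1779 in proximal tubule-like and 1406 in ureteric epithelium-like cells. Leaving out each library in turn gave 2538 to 6488 genes in all cells, 1569 to 2630 in nephron progenitor-like, 1574 to 2659 in proximal tubule-like and 768 to 3326 in ureteric epithelium-like cells. For these moves the cause was not tested. Of 178 values for the shares of 12 classes, 147 kept both, 24 newly passed and 7 reversed. Classes passing numbered 1 at Leiden resolution 0.5, 1 at 2.0, 3 with the stricter filter, 4 with variable genes without cell cycle lists, 4 with each library clustered alone, 1 with variable genes without called genes, 5 without urothelium-like and smooth muscle-like cells, and 0 (without day 5 replicate 2) to 3 (without day 5 replicate 1) without each library in turn. The leukocyte share, not called, reversed with the stricter filter (log2 0.0130), TMM on cell numbers (0.0848), without urothelium-like and smooth muscle-like cells (0.00162) and without day 9 replicate 2 (0.211, in a range from -0.444). The stroma share, not called, reversed with the first 3 of these (0.0468, 0.04999 and 0.0153). Same-numbered libraries share only a number: their deviations correlated, across genes, which are not independent, at 0.07, 0.06, 0.04, 0.05, 0.10 and -0.02 in all, nephron progenitor-like, podocyte-like, proximal tubule-like, stroma-like and ureteric epithelium-like cells. In that order the replicate block called 7640, 4162, 4359, 3450, 8788 and 1936 genes and 16, 4, 10, 14, 10 and 10 lists, with 0 classes by share. In all cells it lost the urothelium list (adjusted p = 0.0783) and added the mural and smooth muscle list (0.0458), in podocyte-like cells it lost the Wnt/beta-catenin list (0.0550), and in proximal tubule-like cells it added oxidative phosphorylation (0.0431).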

Other observations

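The tests of the glucocorticoid-induced and fetal growth gene lists were chosen only after the result was seen.

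The 3 clusters without a name held 858, 556 and 177 cells. The first, with a median of 3429 UMIs, held 0 day 5 cells and 8.90% of day 9 cells. The next, led by the early response genes Klf2, Atf3, Fos, Junb and Dusp1, held 1 cell at day 5 and 555 at day 9, and the last had a median of 5665 UMIs. Among other classes, Venus had a UMI in 86.2% of urothelium-like and 29.0% of endothelium-like cells, and tdTomato in 25.2% of nephron progenitor-like, 27.5% of podocyte-like, 30.0% of committing nephron-like, 18.8% of loop of Henle-like and 0.896% of ureteric epithelium-like cells.

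Zbtb16, which glucocorticoids are known to induce, rose by 5.25 ± 0.33 in podocyte-like, 5.24 ± 0.33 in proximal tubule-like, 9.68 ± 0.24 in stroma-like and 2.91 ± 0.58 in ureteric epithelium-like cells (edgeR adjusted p = 0.00837 for the last), and was at -0.44 ± 0.36 in nephron progenitor-like cells (adjusted p = 0.406). A candidate explanation, held as a hypothesis, is a glucocorticoid response in the first 3 of these classes. Of 17 other glucocorticoid-induced genes, 11 rose and 2 fell in podocyte-like cells (camera adjusted p = 1.39e-04), 11 rose and 3 fell in stroma-like (0.0103) and 8 rose and 3 fell in proximal tubule-like cells (0.0322). In that order Fkbp5 rose by 3.55, 1.56 and 3.00 and Ddit4 fell by -3.03, -1.89 and -1.95. Sgk1 fell in podocyte-like (-1.75) and stroma-like cells (-1.56), Cdkn1a in stroma-like cells (-1.10), and Mt2 (-3.73) and Mt1 (-2.97) in proximal tubule-like cells. The list did not pass in nephron progenitor-like cells (adjusted p = 0.681), nor in ureteric epithelium-like cells (0.373), where Zbtb16 rose. Fry passed in the 3 classes (adjusted p = 0.00663, 0.00607 and 0.0236 in podocyte-like, stroma-like and proximal tubule-like cells) and not in nephron progenitor-like (0.203) or ureteric epithelium-like cells (0.863). With camera and an estimated correlation the highest adjusted p of the 3 classes was 0.168, so a glucocorticoid response cannot be told apart from other change with day and medium.

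Igf2, a fetal growth factor gene, fell in all 6 populations, from -1.02 ± 0.17 in all cells to -3.15 ± 0.18 in ureteric epithelium-like cells, and H19 fell in the 5 classes (edgeR). A candidate explanation, again a hypothesis, is a fall of a fetal growth gene network. Of the fetal growth genes apart from Igf2 and H19, 9 of 13 fell and 1 rose in all cells (camera adjusted p = 3.25e-05), 8 of 12 fell and 1 rose in podocyte-like (3.23e-04) and 10 of 13 fell and 1 rose in stroma-like cells (1.97e-06). None rose and 8 of 13 fell in nephron progenitor-like (5.84e-06), 5 of 13 in proximal tubule-like (0.00222) and 12 of 13 in ureteric epithelium-like cells (5.58e-10). Fry, which allows for correlation between members but does not set them against other genes, passed in all 6 populations (adjusted p from 0.00432 to 0.0189). Camera with an estimated correlation (adjusted p up to 0.167) also decides nothing. A fall of this network stays untested apart from the medium.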
